A study of Caenorhabditis elegans with 2 samples.

How the data were processed

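Chromatin immunoprecipitation followed by sequencing was performed on whole L1 larvae of *Caenorhabditis elegans* hermaphrodites carrying a stably inserted NHR-20 transgene. NHR-20 is a member of the large nuclear hormone receptor family of nematodes, and the transgene adds GFP and FLAG tags to the C-terminus of the protein. Per the labels, chromatin was fragmented by sonication, the tagged receptor was precipitated with an antibody against GFP, and larvae were collected 6 hours after synchronization at the starved L1 stage. The series holds 1 group of 2 biological replicates, so no comparison between groups was possible. 

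The authors deposited lists of regions in narrowPeak form on the ce10 and ce11 builds, and per the notes deposited with the samples each replicate was compared with the same control alignment. For each replicate and for the pooled replicates there is a list of 30000 candidate regions, and a thresholded list was kept after the authors' analysis of the irreproducible discovery rate. The aligner, the peak caller and the rate used as threshold are not given in the sources used here. Each region carries a signal value that the authors' caller assigned relative to the control, and the deposited column of −log10 q-values reaches 4.18 in the pooled list. All 6423 thresholded regions share that highest q-value, so they were ranked by signal. The files give no read totals, so the sequencing depth of the replicates is unknown, and signal sizes were compared only within a list. Between lists, ranks and correlations were used. Control reads were not analysed here.

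The ce11 lists were the main data, since the reference genome used here (WBcel235) is that build. The thresholded list holds exactly the 6423 pooled candidate regions of highest signal, from 6375 distinct intervals because some intervals contain more than 1 summit. The summit was the unit of analysis. Gene models were those of Ensembl release 115, with gene symbols taken from the RefSeq annotation of the same assembly through WormBase identifiers, a choice made after copies of a gene were seen to share symbols in the first source. There were 19973 protein-coding genes on chromosomes I to V and X.

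A summit was assigned to the promoter of a gene when it lay from 1000 bp upstream to 300 bp downstream of any annotated protein-coding transcript start. Remaining summits were classed, in order, as 5′ UTR, 3′ UTR, coding exon, intron, other gene or intergenic. Shares were compared with 1000 circular shifts of all summits along each chromosome by a two-sided permutation test, for which 0.002 is the smallest p-value possible. Chromosome counts were compared with chromosome length by a two-sided exact binomial test, as was the central 50% of each autosome, a single test. The 23 gene lists, the rules for naming genes, the motifs and most alternatives were fixed before the data were examined. List membership was tested against promoter summits with a two-sided Fisher's exact test over all protein-coding genes. For 15 fixed motifs, the 200 bp around each summit were paired with a window of the same width 500 bp away, on a side drawn at random with a fixed seed, and discordant pairs were tested with a two-sided exact sign test. Benjamini-Hochberg adjustment was made within each family of tests, over 7 location classes, 6 chromosomes, 23 lists and 15 motifs, with a threshold of 0.05. These p-values treat summits or genes as units within 1 set of peaks and do not measure variation between animals.

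A thresholded peak counted as found in a replicate when a summit among the replicate's 6423 strongest regions lay within 200 bp. Intervals on shares are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only. Genes named in the text were nhr-20 and unc-119, the genes at the 25 strongest peaks, the 4 strongest members of each enriched list, the 2 strongest of each depleted list, the strongest member of the remaining lists and the 5 genes with most promoter summits. Genes named outside that rule were chosen after their values were seen, and this is said where they appear.

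The tests were tried on simulated data. With 10% of 6423 uniform summits moved to transcript starts, the promoter share was called in 20 of 20 simulated sets, and in 0 of 20 sets without moved summits. Over 19973 genes, 200 were seeded at 4 times the background odds of a promoter summit. The list test called 116 of 164 lists in which at least 50% of members were seeded and 6 of 752 lists with no seeded member. The receptor site AGGTCA planted in 5% of summit windows was called in 10 of 10 sets, against 0 of 10 with nothing planted. Simulated summits were placed uniformly, so they lacked the difference in base composition between real summits and flanks. These sets therefore do not measure false calls that come from composition. In the list simulation each gene was drawn independently of the others. Of the 3609 real promoter summits, 891 lay in windows of more than 1 gene, so the list simulation does not measure false calls that come from shared peaks.

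Alternatives were the peaks above the median signal, wider and narrower promoter windows, each replicate's list alone, nearest-gene assignment, other backgrounds and null models for the lists, other control windows for the motifs, other definitions of a shared region, and the ce10 lists. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.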

Results

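Binding of the tagged nuclear hormone receptor NHR-20 was mapped in whole *C. elegans* L1 larvae 6 hours after synchronization, in 1 group of 2 biological replicates. The thresholded ce11 list held 6423 summits with signal values from 85.96 to 2711 and a median of 169.5. Candidate lists held 30000 regions per replicate, with median signal values of 21.6 in replicate 1 and 16.01 in replicate 2. Signal values are the authors' own and come from the pooled list unless a replicate is named.

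The locus of the tagged receptor was examined first. The strain carries extra nhr-20 sequence and an unc-119 rescue marker, a gene needed for normal movement, so local signal at both genes was read with that in view. nhr-20 (WBGene00003619, chromosome III, 4230436 to 4233219, minus strand) had no summit in its promoter window. The intergenic DNA upstream of it held the third strongest peak of the genome (III, 4237594 to 4238157), with its summit 4663 bp upstream of the annotated start and a signal of 2318. It ranked 3 in replicate 1 and 5 in replicate 2. Further summits lay 1588 bp upstream (signal 568) and 3214 bp upstream (signal 383). Within 50 kb of nhr-20 there were 16 thresholded summits, where the genome-wide density gives 6.58. A second very strong peak in that window, 48930 bp upstream of nhr-20 (III, 4281868 to 4282645, signal 2226), lay 1925 bp upstream of sup-26, which is its nearest gene. At unc-119 (WBGene00006843, III, 10902641 to 10908935) the signal was weak. The 3 thresholded summits within 20 kb ranked 4552, 6032 and 6175, the latter pair in introns of unc-119 itself, with signals of 122, 91.5 and 89.3 against a genome-wide density of 2.97 summits per window.

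**Figure D1:**
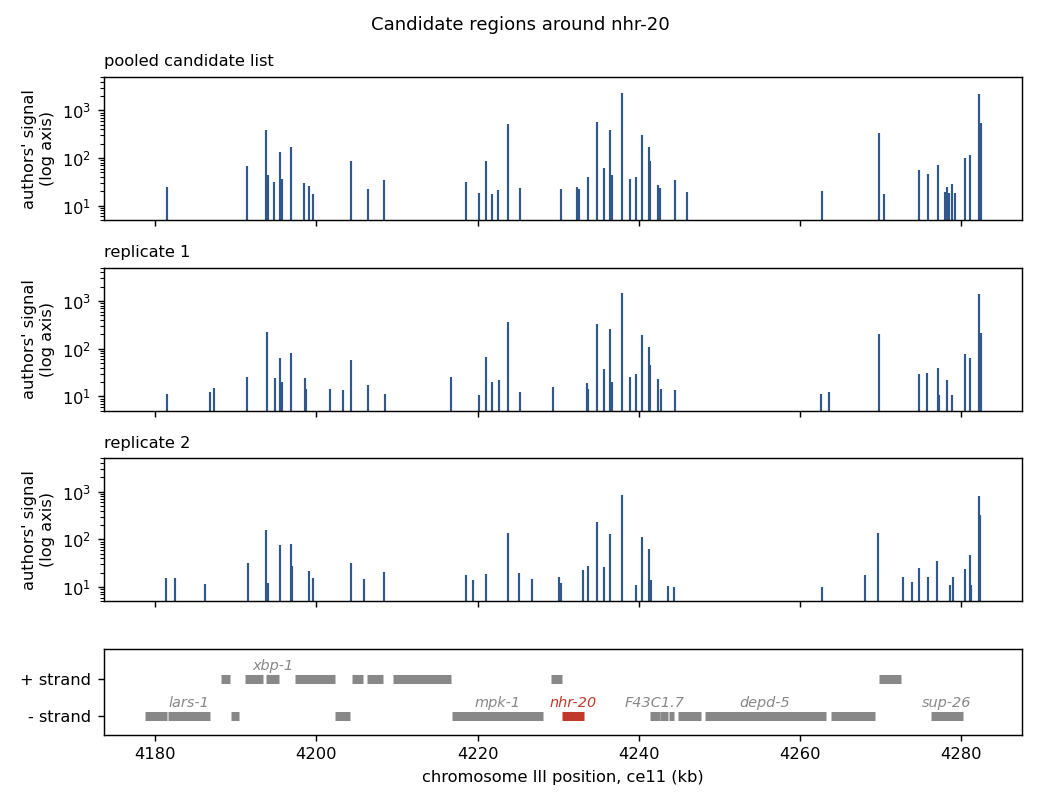
Candidate regions within 50 kb of nhr-20 on chromosome III (ce11 position in kb), each line a summit with the authors' signal on a log axis, for the pooled list and each replicate, above the protein-coding genes of each strand. The tallest line, at 4237882, lies between nhr-20 (red) and F43C1.7, with pooled signal 2318.

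The strongest peaks of the genome lay at varied genes, 4 of the first 25 at promoters of ribosomal protein genes. The peak of highest signal in the pooled list and in both replicates (III, 3867354 to 3867762, signal 2711) had its summit 283 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Peaks followed in the first 14 ranks at the promoters of rpl-18A, shared with Y17G9B.5 (IV, 4749880 to 4750240, signal 2220), rpl-35 (III, 7854532 to 7854865, signal 1935) and rpl-15, shared with K11H12.8 (IV, 654760 to 655079, signal 1873). The second strongest peak (II, 9603350 to 9603882, signal 2554) lay in an intron of the receptor gene nhr-19, 1624 bp downstream of its nearest start. The eighth (V, 7089200 to 7089627, signal 2136) was intergenic, 2190 bp downstream of the nearest start of nhr-286 and outside that gene.

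Of the 25 strongest peaks, 14 had a summit in a promoter window, 5 lay in introns and 6 between genes. Promoter peaks included cdc-48.1, an AAA ATPase that handles ubiquitinated proteins (II, 10563423 to 10563741, signal 2174), puf-9, a Pumilio-type RNA-binding protein (X, 5840959 to 5841502, signal 2164), and iff-2, translation factor eIF5A, shared with F54C9.14 (II, 8561273 to 8561623, signal 1893). The others lay at tasp-1 with K01G5.10 (signal 2130), egg-5 (signal 1920), H41C03.3 (signal 1766), nhl-2 with tag-340 (signal 1637), tos-1 (signal 1621), serp-1.1 (signal 1546) and ztf-7 (signal 1495). The intronic peaks besides nhr-19 were in the autophagy gene epg-9 (IV, 2602002 to 2602391, signal 1745), in Y111B2A.12 (signal 1699) and, 2 of them, in pqn-41 (signals 1634 and 1554). An intergenic peak 1992 bp upstream of hif-1, the hypoxia-inducible factor, had a signal of 2109 (V, 20778186 to 20778664). Others had as nearest protein-coding genes irld-18 (signal 1647, 13381 bp upstream of its start) and ins-13 (signal 1524, 1305 bp downstream of its start). The peaks at egg-5, H41C03.3 and ins-13 lay closer to sls-2.4, sls-2.1 and sls-2.2, genes for the spliced leader SL2 RNA that were singled out after their values were seen. The peak summits, at 4172150, 5844807 and 5543559, lay just upstream of the sls-2 starts at 4172206, 5844865 and 5543598. From the starts of egg-5, H41C03.3 and ins-13 the summits were 561, 970 and 1305 bp away. These peaks therefore cannot be assigned to those genes rather than to the sls-2 genes.

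The replicates were compared to learn how far the binding map was shared. Strong regions such as those at rpl-3, nhr-19 and nhr-20 ranked among the 6423 strongest regions of both, and weak ones often did not. Of the 6423 thresholded summits, 93.2% (95% interval 92.5 to 93.8) had a counterpart among the strongest regions of replicate 1, 86.7% (85.8 to 87.5) in replicate 2 and 80.5% (79.5 to 81.5) in both, against 1.95% in both on average and at most 2.58% in 1000 circular shifts. With the peaks in 4 groups of near-equal size by strength, 99.8% of the strongest group were matched in both replicates, 99.0% of the next, 87.9% of the third and 35.3% (32.9 to 37.7) of the weakest. A match needed a place among the replicate's 6423 strongest regions, so weak peaks can drop out by rank alone. With all candidate regions, 98.5% of the thresholded summits were matched in both replicates. Across the 6326 peaks with a candidate summit within 200 bp in each replicate, the signals of the replicates had a Spearman correlation of 0.814 (bootstrap 95% interval 0.804 to 0.824) and a Pearson correlation of 0.848 on the log2 scale. Peaks are not independent replicates, the thresholded list was drawn from these libraries pooled, and both replicates shared a control, so these values are not an independent estimate of reproducibility. Of the 6423 strongest regions of each replicate, 83 in replicate 1 and 126 in replicate 2 had no candidate within 500 bp in the other. None of the 83 was among the 1000 strongest regions of replicate 1, whereas 5 of the 126 were among those of replicate 2. The strongest, singled out after its value was seen, lay at the promoter of rab-18 (III, 1080652 to 1080856) and ranked 278 in replicate 2. It ranked 300 in the pooled list, and the missing region in replicate 1 does not show that signal was absent there.

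Versions of the lists on both builds held nearly the same regions. The ce10 list had 6428 thresholded regions against 6423 on ce11, and 98.1% of the ce11 regions had a ce10 region on the same chromosome with equal width and equal signal to 4 significant digits. With exact signal values, 0 of the 6423 matched.

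Summits were concentrated in promoters and scarce in coding sequence. Promoter windows held 3609 summits, 56.2% of all (54.96 to 57.4), which was 2.02 times the mean of the circular shifts (27.8%). Coding exons held 72 summits, 1.12% (0.878 to 1.41) against 17.7% in the shifts. Introns held 14.7% against 26.4%, 3′ UTRs 0.763% against 2.58%, and intergenic DNA 24.1% against 21.8%. Each of these shares lay outside the range of all 1000 shifts (permutation test, p = 0.002, the smallest the shifts can give, adjusted p = 0.0028). Genes of other types held 2.76% against 3.38% (permutation test, adjusted p = 0.042), and the 5′ UTR share did not pass the test. The class of other genes pools all types, pseudogenes included, and counts only summits inside those genes and outside protein-coding genes and their promoter windows. It therefore does not show that summits avoid non-coding genes, which are counted by type with a window further below. The median distance from a summit to the nearest protein-coding transcript start was 610 bp.

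**Figure D2:**
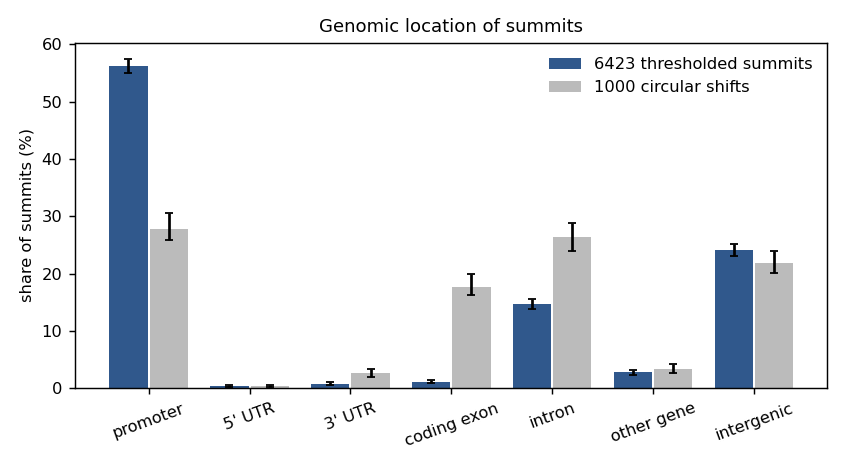
Share of summits (%) in each location class for the 6423 thresholded summits (blue, bars show exact 95% intervals) and the mean of 1000 circular shifts (grey, bars show their full range). Promoters hold 56.2% of summits against 27.8% in the shifts, and coding exons 1.12% against 17.7%.

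Summits were enriched on the X chromosome and in the centres of the autosomes. X held 1396 summits, 1.23 times (1.17 to 1.29) the number its length gives (exact binomial test, adjusted p = 6e-16), and chromosome III held 1.07 times (1.01 to 1.13, exact binomial test, adjusted p = 0.047). Chromosomes IV and V held fewer, at 0.834 (0.785 to 0.885) and 0.887 (0.842 to 0.934) times the number by length. Chromosomes I and II did not pass the test. The central 50% of each autosome held 65.1% (63.8 to 66.5) of 5027 autosomal summits (exact binomial test, p = 8.3e-104). On X that share was 53.5%. Counted by gene, 22.4% of the 2731 protein-coding genes of X had a promoter summit, against 20.6% over all chromosomes, 16.9% on V and 25.6% on III. These shares were not tested against each other. The binomial test takes summits as independent, although they cluster.

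In all, 4121 of 19973 protein-coding genes (20.6%) had a promoter summit, 2.30 times the 1789 genes of an average circular shift (permutation test, p = 0.002, the smallest the shifts can give). Of the 3609 promoter summits, 891 lay in windows of more than 1 gene, and 375 genes had 2 or more summits. The most summits were at egl-27, a homolog of the chromatin protein MTA (6 summits, strongest signal 429). srh-2, a chemoreceptor-type gene, had 4 summits (strongest signal 1266), as did din-1, which encodes a corepressor of the receptor DAF-12 (546), C34B4.2 (510.4) and the zinc finger gene somi-1 (217).

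Several lists of housekeeping genes had promoter summits often, and by promoter window ribosomal protein genes had the highest share. Of 78 ribosomal protein genes 69 had a promoter summit, 88.5% (79.2 to 94.6) against 20.4% of other genes (odds ratio 29.97, 95% interval 14.9 to 68.3, Fisher's exact test, adjusted p = 9.0e-37), led by the rpl-3, rpl-18A, rpl-35 and rpl-15 peaks given above. With nearest-gene assignment that odds ratio was 3.77, under that of body wall muscle genes (11.9), and with a candidate background it was 15.1. No immunoprecipitation from worms without the tag was analysed here, so a summit at these and the following genes does not by itself show binding by NHR-20. Of 33 proteasome genes 22 had a promoter summit (odds ratio 7.73, 3.59 to 17.7, Fisher's exact test, adjusted p = 4.6e-08), with the strongest peaks at the regulatory particle genes rpn-3 (signal 966), rpt-2 (549.5), rpn-9 (465) and rpn-11 (456). Of 71 heat shock and chaperone genes 39 had a promoter summit (odds ratio 4.72, 2.88 to 7.80, Fisher's exact test, adjusted p = 1.2e-09). Their strongest members were dnj-13 (signal 1244), hsp-60, the mitochondrial chaperonin (1242), hsp-1, a constitutive HSP70 (1173), and hsp-90 (1166). Of 60 autophagy and lysosome genes 34 had a promoter summit (odds ratio 5.06, 2.95 to 8.80, Fisher's exact test, adjusted p = 3.8e-09), with lgg-2 (1271) and lgg-1 (830), the ATG8 homologs, epg-7 (992) and vha-12 (766), a subunit of the vacuolar proton pump, in front. Cell cycle and DNA replication genes had a promoter summit in 32 of 54 cases (odds ratio 5.63, 3.17 to 10.2, Fisher's exact test, adjusted p = 2.9e-09). With a candidate background the odds ratio was 2.84 for proteasome, 2.32 for autophagy and lysosome, 2.76 for cell cycle and 3.16 for chaperone genes. The cell cycle genes were led by rfc-4, a subunit of the clamp loader (signal 988), pcn-1, the sliding clamp PCNA (854), the E2F homolog efl-1 (751) and the retinoblastoma homolog lin-35 (731). Some of these peaks were shared. Among genes singled out after their values were seen, eef-1A.1 shared the rfc-4 peak and the chaperone gene hsp-110 the rpn-3 peak. The rpn-3 peak therefore counts in both the proteasome and the chaperone list. Peaks at dnj-13, hsp-60 and hsp-90 also lay in promoter windows of other genes.

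Nuclear hormone receptor genes and metabolic gene families were enriched too, by promoter window at lower odds ratios. With nearest-gene assignment that order did not hold, since lipid genes (3.77) stood above chaperone (2.48), proteasome (3.18), autophagy (3.39) and cell cycle genes (3.65). Of 274 receptor genes 105 had a promoter summit, 38.3% (32.5 to 44.4, odds ratio 2.43, 1.88 to 3.12, Fisher's exact test, adjusted p = 1.2e-10). With a candidate background the receptor odds ratio was 1.69 (Fisher's exact test, adjusted p = 0.0020), the lowest value for that list in any alternative. The strongest promoter summits of receptor genes lay at nhr-68, which acts in propionate metabolism (V, 11572835 to 11573254, signal 1273), nhr-35 (866), nhr-34 (771) and nhr-47 (769.9). The nhr-68 peak also lay in the promoter window of H12C20.7, a gene singled out after its value was seen. Of 99 fatty acid and lipid genes 41 had a promoter summit (odds ratio 2.74, 1.79 to 4.16, Fisher's exact test, adjusted p = 6.1e-06). They were led by acs-2, a fatty acyl-CoA synthetase (V, 15566501 to 15566868, signal 773), the acyl-CoA dehydrogenase acdh-9 (579.6), the acyl-CoA oxidase acox-3 (559) and the carnitine palmitoyltransferase cpt-2 (539.6). The detoxification families also passed. Cytochrome P450 genes had a promoter summit in 29 of 75 cases (odds ratio 2.43), with cyp-13A8 (signal 584), cyp-13A5 (483) and the divergent pair cyp-33C7 and cyp-33C6, which share a peak (466), ahead. Glutathione S-transferases had a promoter summit in 18 of 49 (odds ratio 2.24), led by gstk-1 (614), gst-20 (521), gst-7 (493) and gst-27 (468), and UDP-glucuronosyltransferases in 23 of 67 (odds ratio 2.02), led by ugt-20 (697), ugt-13 (414), ugt-64 (385) and ugt-58 (332). Core histone genes had a promoter summit in 23 of 74 (odds ratio 1.74, Fisher's exact test, adjusted p = 0.044), with his-37 (1343), the H2A.Z gene htz-1 (759) and the pair his-67 and his-68, which share a peak (726), in front. The calls for lipid genes and for the P450, transferase and histone families were less firm. The lipid odds ratio was 1.77 with a candidate background (Fisher's exact test, adjusted p = 0.042) and 1.82 among the peaks above the median signal (0.044). Against genes with any candidate region in the promoter window the odds ratio was 1.39 for P450 genes (Fisher's exact test, adjusted p = 0.37), 1.22 for glutathione S-transferases (0.71) and 0.956 for UDP-glucuronosyltransferases (0.89), but 3.72 for histones (0.0027). Among the peaks above the median signal the P450 (1.79), UDP-glucuronosyltransferase (1.56) and histone (1.39) calls were lost, and with strata of upstream distance the histone call was lost (1.15). Without replicate 2 the histone (odds ratio 1.52, Fisher's exact test, adjusted p = 0.16) and UDP-glucuronosyltransferase (1.75, adjusted p = 0.073) calls were lost, and with nearest-gene assignment the histone odds ratio was 0.787. With the wider promoter window the histone (1.52) and UDP-glucuronosyltransferase (1.67) calls were lost as well. Of 11 alternatives, the call held in 5 for histones, 6 for UDP-glucuronosyltransferases, 9 for P450 genes and 10 for glutathione S-transferases.

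Among tissue markers only the body wall muscle list passed the test. Of its 36 genes 22 had a promoter summit (61.1%, 43.5 to 76.9, odds ratio 6.07, 2.97 to 12.8, Fisher's exact test, adjusted p = 4.1e-07), led by the calponin gene cpn-3 (signal 533), unc-112, a kindlin of muscle attachments (296), the actin gene act-4 (227) and tnt-2, a troponin T (199). Among the peaks above the median signal that call was lost (odds ratio 1.43, Fisher's exact test, adjusted p = 0.53). Intestine markers had a promoter summit in 8 of 33 cases (strongest ges-1, signal 212), hypodermis markers in 8 of 37 (col-10, 312), pan-neuronal markers in 6 of 33 (unc-16, 492), pharynx markers in 4 of 29 (peb-1, 261), germline markers in 4 of 36 (cgh-1, 411) and glia and excretory markers in 3 of 25 (vha-8, 712). Insulin signalling and starvation arrest genes had a promoter summit in 12 of 37 (nhr-68 strongest), which did not pass (odds ratio 1.85, Fisher's exact test, adjusted p = 0.14), and 20 of these genes belong to other lists too. The insulin list passed with nearest-gene assignment (odds ratio 2.88) and with the wider promoter window (2.66), and the intestine (2.20) and pan-neuronal (3.18) lists passed with nearest-gene assignment. Set against circular shifts the insulin (2.42 times the shift mean) and intestine lists (2.69) also passed, where protein-coding genes in general stood at 2.30.

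Chemoreceptor-type G protein-coupled receptor genes had promoter summits least often of the lists, in 27 of 1309 cases, 2.06% (1.36 to 2.99, odds ratio 0.0750, 0.0491 to 0.110, Fisher's exact test, adjusted p = 2.4e-94). The strongest of them were srh-2 and srh-16 (signal 521). The chemoreceptor odds ratio was 0.162 with a candidate background and 0.0366 with the narrower promoter window. Neuropeptide genes had a promoter summit in 13 of 152 (odds ratio 0.358, 0.186 to 0.633, Fisher's exact test, adjusted p = 0.00017), the strongest being ins-39 (675) and nlp-31 (456). Homeobox genes had a promoter summit in 9 of 91 (odds ratio 0.421, 0.186 to 0.840, Fisher's exact test, adjusted p = 0.016), led by ceh-38 (769) and ceh-20 (257), and cuticle collagens in 23 of 176 (odds ratio 0.576, 0.354 to 0.898, Fisher's exact test, adjusted p = 0.018), led by col-38 (681) and col-63 (331). Circular shifts give 2.30 times the shift mean for protein-coding genes in general. Chemoreceptor genes stood at 0.277 times the shift mean, homeobox genes at 0.968, neuropeptide genes at 1.00 and collagens at 1.63, each under the value for genes in general. The homeobox call was lost with nearest-gene assignment (odds ratio 0.613) and with strata of upstream distance (0.465). It held at lower odds ratios among the peaks above the median signal (0.160) and with a candidate background (0.296). The collagen call was lost with the peaks above the median signal (0.813), with those matched in both replicates (0.631, an alternative chosen after seeing the data) and with a candidate background (0.759).

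**Figure D3:**
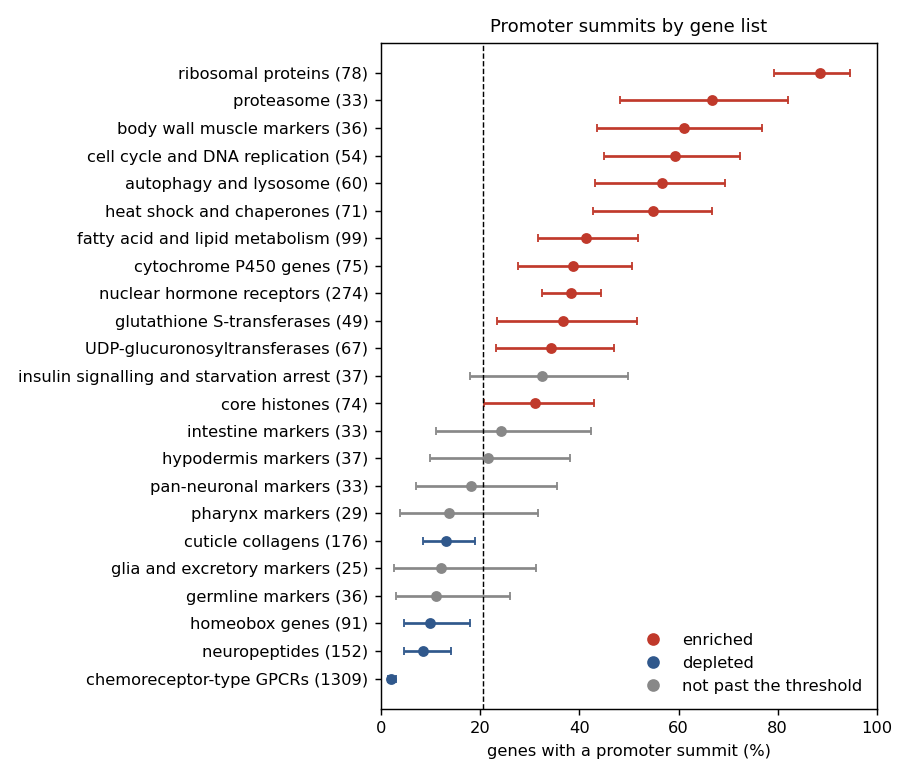
Share of genes with a promoter summit (%, point) in each of 23 gene lists, with the exact 95% interval and the number of genes in parentheses. The dashed line marks 20.6%, the share over all protein-coding genes, and lists run from ribosomal proteins at 88.5% down to chemoreceptor-type GPCRs at 2.06%.

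The sequences under the summits were searched for 15 fixed motifs. Of these, 10 were more frequent at summits than in flanks, 4 less frequent and AP-1 did not pass. The largest ratio of pairs with the motif only at the summit to pairs with it only in the flank was 13.3, for CTGCGTCT, which occurred in 12.3% of summit windows and 1.03% of flanks (exact sign test, adjusted p = 2.1e-161). The GAGA repeat GAGAGAGA followed at 11.1% against 1.21% (ratio 10.2, exact sign test, adjusted p = 5.5e-132) and the E-box CACGTG at 11.6% against 3.74% (ratio 3.45, exact sign test, adjusted p = 9.6e-65). With promoters that lacked a peak as control the odds ratio was 6.88 for CTGCGTCT and 5.24 for the GAGA repeat, with a window of 100 bp the CTGCGTCT ratio was 21.9, and with flanks 1000 bp away the GAGA ratio was 6.41. The nuclear receptor site AGGTCA occurred in 8.39% of summit windows against 4.87% of flanks (ratio 1.78, exact sign test, adjusted p = 2.3e-15). The AGGTCA ratio was 1.34 with the peaks above the median signal, 1.39 with flanks 1000 bp away and 2.11 with a window of 100 bp. Against promoters that lacked a peak (6.19%) the AGGTCA odds ratio was 1.39. The tandem copy AGGTCANAGGTCA of this site, with up to 2 mismatches, occurred in 1.18% against 0.732% (ratio 1.62, exact sign test, adjusted p = 0.012). E2F (ratio 2.04), CRE (1.52), GATA (1.41), bHLH (1.39) and forkhead sites (1.11) were also more frequent, and the homeobox site (0.476), the TATA box (0.619), the CCAAT box (0.821) and poly-T (0.466) less frequent. Against promoters that lacked a peak, the GATA odds ratio was 1.13. Summit windows were richer in G and C, at 41.6% ± 6.84 against 35.2% ± 7.13 in flanks (SD over 6423 windows). Set against other orders of their own letters, a test chosen after seeing the data, E2F (73rd percentile), CRE (82.3), bHLH (65), forkhead (92) and the tandem copy (79) stood under the 95th percentile, whereas CTGCGTCT, GAGA, E-box, GATA and AGGTCA stood above it. The less frequent homeobox (61.5th percentile), TATA (85.7) and CCAAT sites (41.4) were not unusually low among orders of their letters, and poly-T has no other order. The tandem copy was not called without replicate 2 (ratio 1.26, exact sign test, adjusted p = 0.20), nor with the peaks above the median signal (1.32), flanks 1000 bp away (1.09), a window of 100 bp (1.22) or promoters without a peak as control (1.25). CRE was not called without replicate 1 (1.36, exact sign test, adjusted p = 0.053). The forkhead site was not called with the peaks above the median signal (1.06) or a window of 100 bp (1.08), and with promoters that lacked a peak as control the forkhead site was less frequent at summits (odds ratio 0.890, Fisher's exact test, adjusted p = 9.5e-05). With flanks 1000 bp away AP-1 passed (ratio 1.56).

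**Figure D4:**
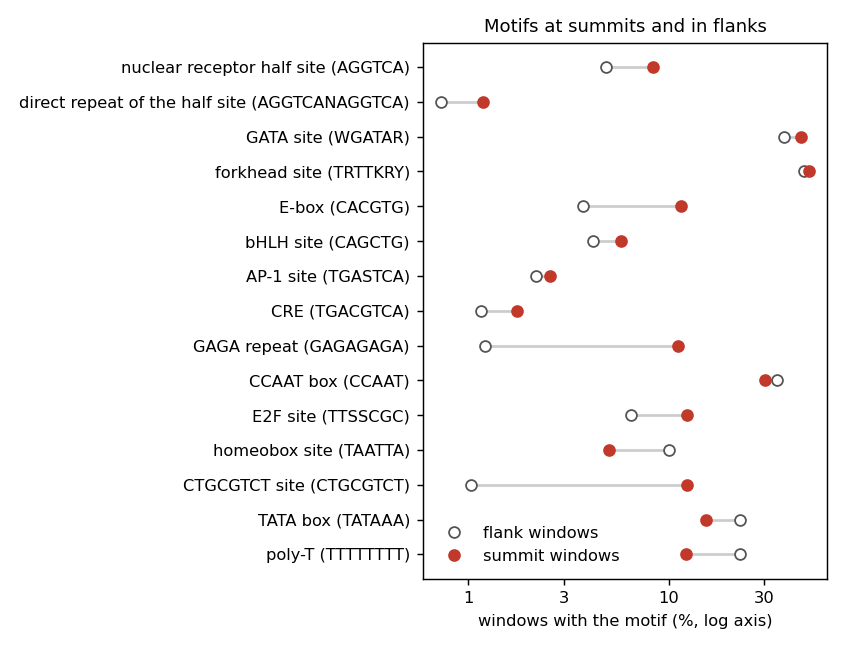
Share of 200 bp windows with each of 15 motifs (%, log axis) at summits (red) and in paired flanks 500 bp away (open circles). CTGCGTCT rises from 1.03% in flanks to 12.3% at summits, the GAGA repeat from 1.21% to 11.1% and the receptor site from 4.87% to 8.39%.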

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

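The tests of non-coding gene classes and of open DNA were chosen after the counts of summits beside those genes had been seen, and so were both tests on subsets of tRNA genes, whose outcomes had not been seen. The comparisons above used protein-coding genes, and summits beside other gene types were outside them. With the same window, 308 of 612 tRNA genes had a summit (50.3%, 46.3 to 54.4), where the circular shifts gave 50.98 genes on average and at most 80. The same held for 152 of 346 snoRNA genes (shift mean 26.8, highest 47), 36 of 129 snRNA genes (9.34, highest 21), 54 of 261 miRNA genes (21.8, highest 42) and 42 of 194 lincRNA genes (15.2, highest 28). Protein-coding genes in general stood at 2.30 times their shift mean, and miRNA (2.47) and lincRNA genes (2.75) lay near that level, while tRNA (6.04), snoRNA (5.68) and snRNA genes (3.85) lay above it. The annotation classes sls-2.1, sls-2.2 and sls-2.4, genes for the SL2 RNA, as snRNA genes. Since 15 of 19 sls-2 genes had a summit, they may carry much of the snRNA excess, and the snRNA share without them was not computed. Pseudogenes had a summit in 73 of 2128 cases, under the lowest shift (105). Each of these 6 classes lay outside all 1000 shifts (permutation test, p = 0.002, the smallest the shifts can give).

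Summits lay close to the tRNA starts, with a median offset of -17 bp (negative is upstream) and 85.7% of 307 within 100 bp. Reads shared between identical tRNA copies were weighed first: of the 140 tRNA genes whose sequence occurs once in the genome 31.4% (23.9 to 39.8) had a summit, above the highest shift (17.9%), which argues against reads shared between identical copies as the whole cause, although the share was higher for genes in several copies (55.9%, 51.3 to 60.5). Copies that differ by a few bases counted as found once, so reads shared between near-identical copies were not excluded. The window can also take in a summit at a neighbouring tRNA gene. Neighbouring protein-coding promoters were weighed next, and 45.6% (39.2 to 52.2) of the 239 tRNA genes over 2 kb from a protein-coding start had a summit against at most 15.1% in the shifts, so such neighbours do not account for the pattern. Recovery of open or strongly transcribed DNA whatever the tagged protein remains a candidate explanation: ribosomal protein genes had promoter summits at an odds ratio of 29.97, but no immunoprecipitation from worms without the tag was analysed here, so it cannot be told apart from binding by NHR-20. No biological explanation was tested, since the design has 1 group.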

How the results depend on the processing

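The alternatives with peaks matched in both replicates, without chemoreceptor genes in the background and with reordered motif letters were chosen after seeing the data. The promoter share of summits stayed above the shifts in each alternative set of peaks or promoter window (44.4% to 70.2%). The X excess (1.198 to 1.24) and the autosomal centre share (64.7% to 65.6%) were tried only with the peaks above the median signal and with each replicate's list alone. Both passed their tests in each of these. Between 8 and 14 lists were enriched, and ribosomal, proteasome, chaperone, autophagy, cell cycle, lipid and receptor lists kept their call in all 11 alternatives, at sizes that moved widely (ribosomal 3.77 with nearest-gene assignment, and proteasome 2.84, autophagy 2.32 and cell cycle 2.76 with a candidate background). Target genes numbered 4057 to 4132 with each replicate's list alone and 2450 with the peaks above the median signal, which are fewer. Their number also moved with the gene assignment, to 5251 with the wider promoter window, 3253 with the narrower and 4565 with nearest-gene assignment. Peaks matched in both replicates gave 3521. With circular shifts 1 list was depleted, not 4, with collagens at 1.63 and neuropeptides at 1.00, but genes in general stand at 2.30 there, so this does not show that they match other genes. With nearest-gene assignment histones were at an odds ratio of 0.787 and pan-neuronal markers at 3.18, and with a candidate background UDP-glucuronosyltransferases were at 0.956. Against promoters without a peak the forkhead site was at 0.890. Only 5 motifs stood at or above the 95th percentile of reordered letters. The cause of these changes was not tested. The share of peaks found in both replicates was 61.4% with 50% reciprocal overlap, 77.9% within 100 bp, 81.8% within 500 bp, 99.4% for peaks above the median signal and 98.5% with all candidates, and the Spearman correlation was 0.829 above the median signal and 0.825 within 100 bp. Signals of the builds matched in 98.1% to 4 digits and in 0 exactly, and a 100 kb window around nhr-20 held 27 summits. The strongest regions of the pooled list are the thresholded list itself, so that alternative was void. No paired analysis was possible because the series has 1 group. Depth is unknown, so what it limits was not measured.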

Other observations

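The tests of the regions around nhr-20 and of the list floor were chosen after its peak was seen, the tests of motifs by strength, by gene list and by letter order after the motif counts were seen, and the genes in this part after their values were seen. SL2 and SL1 RNAs are spliced leaders joined to other transcripts. Of 19 sls-2 genes 15 had a thresholded summit, led by sls-2.4 (I, 4172206 to 4172315, signal 1920), sls-2.1 (1766), sls-2.2 (1524) and sls-2.8 (959), while 0 of 12 sls-1 genes, which form a repeat array on chromosome V, had even a candidate region in the pooled list. The difference was not tested, since several sls-2 genes share a peak and whether reads map uniquely to the sls-1 array is not known. These sls-2 genes overlap the snRNA class counted above, so the SL2 and snRNA results are not separate observations. As at tRNA genes, binding was not separated from recovery of open DNA.

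Motif content changed with peak strength. From the strongest to the weakest of 4 groups of peaks, CTGCGTCT fell from 16.25% to 9.28% (odds ratio 1.90, Fisher's exact test, adjusted p = 1.4e-08), the E-box from 15.3% to 8.41% (odds ratio 1.97, adjusted p = 7.7e-09) and the E2F site from 16.13% to 8.85% (odds ratio 1.98, adjusted p = 3.5e-09), all Fisher's exact tests. The GAGA repeat also fell (odds ratio 1.44). Other sites ran the other way, GATA from 36.9% to 52.7% (odds ratio 0.527, Fisher's exact test, adjusted p = 4.8e-18) and, by odds ratio, AP-1 (0.459), AGGTCA (0.657), poly-T (0.698) and TATA (0.771). The G and C content of the groups was not compared, so these trends cannot be told apart from a change in base composition. Within target promoters, receptor genes carried CTGCGTCT in 24 of 105 cases (22.9%) against 12.9% of other targets, and ribosomal protein genes carried the GAGA repeat in 0 of 69 against 8.29%, but neither passed over 32 tests (Fisher's exact test, adjusted p = 0.095 for both).

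The strong peak upstream of nhr-20 was weighed against extra copies of the transgene segment. In the first test, the median signal of the 24 other candidate regions within 20 kb (35.2) stood at the 67.5th percentile of 10000 random segments that held at least 4 regions, under the 80th percentile set as the bound against extra copies. That test cannot show extra copies, because the candidate list ends at a floor: with all signals doubled the median was 66.6, and without doubling the regions over the same floor had a median of 75.6. The number of regions, taken as a second test with the same bounds after it and the first outcome were known, stood at the 92.0th percentile (24 against a median of 11), between the bounds of 80 and 95. Extra copies therefore cannot be told apart from binding there, and no biological explanation was tested.

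The site AGGTCA is one that many nuclear receptors recognise, and its excess at summits could come from base composition or from recognition by the receptor. Its summit-to-flank ratio of 1.78 stood at the 99th percentile of 100 other orders of its letters, which argues against composition alone. The site was less frequent in the strongest of the 4 groups of peaks (6.48%) than in the weakest (9.53%, odds ratio 0.657, 0.502 to 0.858, Fisher's exact test, adjusted p = 0.0027). A rise of the site with peak strength, which recognition was taken to predict, was therefore not seen. Strong peaks could not be separated from recovery of open DNA here, so signal may not follow occupancy by the receptor. The contrast by strength therefore cannot decide on recognition, and recognition at weaker peaks was not tested.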
